A study of Homo sapiens with 10 samples.

How the data were processed

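Gene expression was measured in 10 human T-cell acute lymphoblastic leukaemia (T-ALL) cell lines, 1 array per line, on a custom Agilent 1-colour array that carries catalogue probes for known genes beside probes for long non-coding RNAs. Per the labels' protocols, the cells were grown in RPMI with 10% serum, except ALL-SIL with 20%, total RNA was column-purified with DNase digestion, and 100 ng of it was converted to Cy3-labelled complementary RNA. A label for the cell type divides the lines into TLX (DND-41, HPB-ALL and ALL-SIL), TAL (PF-382, JURKAT, KE-37 and CCRF-CEM), IMM (LOUCY alone) and other (KARPAS-45 and PEER). The lines are separate cell lines with 1 array each, so p-values of the group comparisons of single features measure the spread between lines of a group, and technical repeats of a line were not available to set against it. The number of arrays limits the precision of every value.

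The scanner files hold the authors' deposited spot intensity, in arbitrary linear units, extracted with Agilent Feature Extraction 10.7.1.1 per the file headers; the submitters' processing notes name version 9.1 of the same program, and the reason for the difference is not given in the sources used here. The processed intensity is background-subtracted and detrended within each array, per the file headers, with no normalization between arrays. The same files give, per the file headers, other values that were used: 0 or 1 flags for a spot well above background, saturated or non-uniform, and the raw median intensity of the spot and of its local background. A second deposited table holds the authors' own log2 values for 37275 probes. Set against the log2 signal of its own array, each column of the deposited values correlated at 0.994 to 0.996, and at most 0.946 with any other array, so scale and direction are settled, while the normalization method, the treatment of dim probes and the choice of probes are not given in the sources used here. The medians of its columns were 7.20 for LOUCY, 7.03 for KARPAS-45, 7.04 for PEER, 7.09 for DND-41, 7.12 for HPB-ALL, 6.98 for ALL-SIL, 7.22 for PF-382, 7.36 for JURKAT, 7.26 for KE-37 and 7.00 for CCRF-CEM. This table was used only as an alternative.

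Each array held 61537 non-control spots of 57176 distinct probes. The share of spots well above background ran from 47.8% in CCRF-CEM to 55.2% in LOUCY, with a median of 53.0%, and 0 spots were saturated. As more than 50% of the spots of the median array were detected, log2 of the processed intensity was scaled by subtracting the 75th percentile over all non-control probes of the array, which lay between an intensity of 401 in KARPAS-45 and 729 in HPB-ALL. A level of 0 in the text is thus a signal at that percentile. Non-uniform spots were left out and the spots of a probe were averaged.

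Gene symbols were assigned from RefSeq accessions through a RefSeq gene table of assembly GRCh38.p14, used for names and for the order of genes only; no positions are given, because the array design is built on hg19. Of the 34134 catalogue probes, 25728 matched a symbol and 8406 did not, which gave 19721 symbols, 18143 of them protein-coding and 1027 long non-coding. The 23042 custom probes carry transcript identifiers, 22990 of them of the Ensembl or TCONS kind, which the sources used here do not pair with symbols, so they were treated as long non-coding features and at most 2 identifiers that were higher and 2 that were lower are printed. A feature is a gene symbol, represented by its probe with the highest mean over the 10 arrays, or an unnamed probe.

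TLX was compared with TAL by limma 3.58.1 (lmFit and eBayes, two-sided, R 4.3.3 with version 1.17.8 of data.table) on the 7 arrays of these groups, over features well above background on at least 3 of them. The lines labelled other were compared with the mean of TLX and TAL in a fit of all 10 arrays with 4 group means, over features well above background on at least 2 of 10. The threshold was a Benjamini-Hochberg adjusted p under 0.05, called past the threshold in the text. LOUCY, the single IMM line, has no replicate, so features were counted whose level lay at least 1 log2 unit outside the range of the other 9 lines, and the same count was made for each other line. Where a probe was not well above background on some or all arrays of the dimmer group, the fold given is a lower bound, written as at least N-fold: the mean of the brighter group is set against the mean of, per array, the higher of the lowest signal well above background and the dim probe's own signal. Similarity of lines was the Pearson correlation across features, tested by an exact permutation over the 35 splits of the 7 TLX and TAL arrays. Shares of long non-coding and coding features were compared by Fisher's exact test, with 95% confidence intervals.

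The groups, the tests, the first set of alternatives, the rule for naming genes and 20 gene lists with 437 genes, of which 410 had a probe, were fixed before the data were examined. The lists were: TAL1 complex and its described targets; NKL-class homeobox genes; HOXA cluster and cofactors; NOTCH1 targets; Cortical thymocyte genes; T-cell receptor and proximal signalling; Early T-cell precursor and stem cell genes; Proliferation; Apoptosis regulators; IL7R, JAK and STAT signalling; Homing and adhesion receptors; Interferon response; MHC class II and its regulators; Recurrently mutated or deleted T-ALL genes; Long non-coding RNAs. Markers of other cell types formed 5 of the lists: Myeloid markers, B-cell markers, NK and cytotoxic markers, Erythroid and megakaryocyte markers, and Stromal and epithelial markers. List shifts between TLX and TAL were tested with camera (preset correlation of 0.01, and again with an estimated correlation) and fry of limma, adjusted over the 20 lists. For LOUCY each list's median was placed among those of 10000 random lists matched on mean expression. Genes of the random lists were drawn independently, so a list of genes that vary together reaches extreme percentiles more readily. The rule named the oncogenes behind the labels in every line, the 10 largest differences each way among called and non-overlapping named features (5 among long non-coding ones), up to 4 called and 2 uncalled members of each list, the 10 largest gaps each way in LOUCY, and the 5 largest differences each way for the lines labelled other.

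Data were simulated for the TLX against TAL comparison, with 200 of 25386 features changed. The same code recovered 24% of the changes of log2 2, 76% of those of 4, 78% of those of 6 and 88% of those of 8. It made 5 false calls there and called 0 features where nothing had been changed. The simulated noise was independent between features, without slide, row or line structure, so these counts do not limit false calls in the real arrays. Alternatives covered normexp background correction (offset 50) followed by quantile normalization, quantile normalization alone, the percentile over probes well above background on all arrays, the deposited log2 table, no filter and a stricter filter on dim probes, other rules for several probes of a gene, a trend and robust prior, a minimum difference, the slide as a block, and leaving out each line in turn. Slide row as a block, slide 1 alone, slide as a block for the lines labelled other, the similarity by class of feature and the list medians of LOUCY in other scalings were added after the data were seen. Normexp was run on the median spot signal in place of the mean spot signal, a column not used here. Slide 1 carried 8 arrays and slide 2 the PEER and CCRF-CEM arrays, which were also scanned on another day, so slide and scan day are 1 factor. The slides have 2 rows of array positions, and LOUCY, KARPAS-45, DND-41 and ALL-SIL lay in row 1 and the other lines in row 2, so that 2 of the 3 TLX arrays and 0 of the 4 TAL arrays lay in row 1. A few genes picked by the naming rule are not reported here. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.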

Results

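Between 47.8% (CCRF-CEM) and 55.2% (LOUCY) of 61537 spots were well above background, 0 spots were saturated, and the number of non-uniform spots ran from 0 in CCRF-CEM to 132 in PF-382. On slide 1 it was 11 to 35 in the row with LOUCY, KARPAS-45, DND-41 and ALL-SIL and 85 to 132 in the row with HPB-ALL, PF-382, JURKAT and KE-37, and the additive error of the scanner file was 2.62 to 3.57 and 4.57 to 6.12. On that slide these signs of quality thus follow the slide row, which in part follows TLX against TAL. PEER and CCRF-CEM, in row 2 of slide 2, had 11 and 0 non-uniform spots. Their additive errors were 3.65 and 4.42, so the pattern was not shown across slides. The genes behind the labels TLX and TAL were examined before any comparison of groups. Levels are log2 signal relative to the 75th percentile of the array.

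TLX3, a homeobox transcription factor, stood at 4.33 in DND-41 and 4.40 in HPB-ALL and was not well above background in the other 8 lines, a difference of at least 791-fold. TLX1, its paralogue, stood at 3.32 in ALL-SIL, at least 372-fold over the mean of the other 9 lines, of which only LOUCY, at -5.16, was also well above background. TAL1, a basic helix-loop-helix transcription factor of blood stem cells, was well above background in the 4 TAL lines and in 0 of the other 6. Its level was 1.91 in JURKAT, 0.86 in KE-37, 0.68 in PF-382 and 0.10 in CCRF-CEM, at least 91.5-fold over the others. Each TLX line thus carried 1 of the 2 TLX genes and each TAL line carried TAL1.

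The partners of TAL1 were spread over several groups. LMO1, a LIM-domain bridging protein, was highest in JURKAT (2.19), KE-37 (1.80) and LOUCY (0.95). LMO2, its paralogue, was highest in PF-382 (4.91), PEER (3.97), LOUCY (3.25) and CCRF-CEM (3.16), followed by HPB-ALL at -0.83. LYL1, a factor related to TAL1, was highest in LOUCY (3.68), PEER (2.48) and CCRF-CEM (0.86). NKX2-1, a homeobox gene of lung and thyroid, stood at 2.05 in JURKAT and was not well above background in the other 9 lines, at least 169-fold. HOXA9, a homeobox gene of early blood progenitors, stood at 2.23 in LOUCY and between -1.38 and -0.27 in the other lines, 8.36-fold over their mean. A second HOXA9 probe stood at 4.99 in LOUCY and -4.28 in JURKAT and was not well above background in the other 8 lines, so the size of the difference depends on the probe. NKX2-5, a heart homeobox gene, read 6.59 to 7.40 in all 10 lines, so its probe did not separate the lines. With 1 array per line these are levels without a test.

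**Figure D1:**
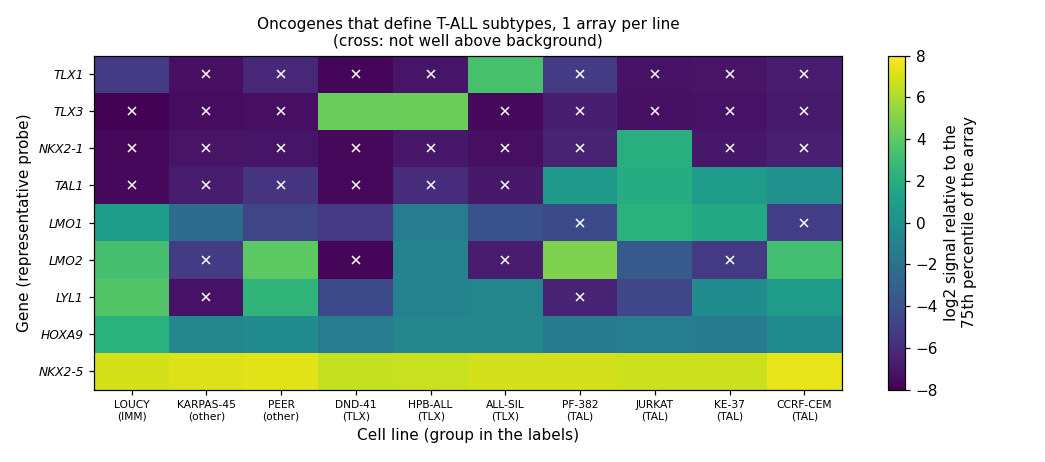
Levels of the oncogenes behind the labels in the 10 lines, as log2 signal relative to the 75th percentile of the array, with crosses where the probe was not well above background. TLX3 stood out in DND-41 (4.33) and HPB-ALL (4.40), TLX1 in ALL-SIL (3.32) and TAL1 in the 4 TAL lines (0.10 to 1.91).

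Among genes past the threshold, the largest losses in TLX included RPL39L, a ribosomal protein paralogue, NDN, a growth suppressor, and PSAT1, an enzyme of serine synthesis. Among the same genes, the largest gains with low levels in TAL were in MSRB3, a methionine sulfoxide reductase, MAP3K8, a signalling kinase, and PCDH9, a cell adhesion protein. Of 25521 features tested, 102 were past the threshold between the 3 TLX and the 4 TAL lines, 9 higher and 93 lower in TLX, and 77 of them had a gene symbol. The median difference was -6.56 among the lower features and 4.01 among the higher ones. Of the 93 lower features, 60 were not well above background on any TLX array, and of the 9 higher ones 5 were not on any TAL array. The lower features were mostly not specific to TAL, since 66 of the 93 were well above background in KARPAS-45, 66 in PEER and 49 in LOUCY. Among the gains named above, MSRB3 and MAP3K8 were low in TAL but not specific to TLX. Each was well above background on 6 arrays, 3 of them TLX and 0 of them TAL. In LOUCY MSRB3 stood at 3.87 and MAP3K8 at 1.35. PCDH9 was well above background on the 3 TLX arrays only.

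MSRB3 rose in TLX by 7.43 (SE 0.54, n = 3 and 4, adjusted p = 0.00341), from -6.29 (SD 0.66) in TAL to 1.13 (SD 0.92), at least 65.8-fold. MAP3K8 rose by 5.72 (SE 0.77, adjusted p = 0.0402), at least 28.5-fold, and PCDH9 by 5.17 (SE 0.35, adjusted p = 0.00220), at least 9.98-fold. KLF6, a zinc finger transcription factor, was present in both groups and rose by 3.78 (SE 0.32, adjusted p = 0.00617), 13.7-fold. Its level went from 2.12 (SD 0.19) to 5.90 (SD 0.53). A second KLF6 probe, also well above background in both groups, gave 1.99, so the size depends on the probe. ETS2, an ETS-family transcription factor, rose by 3.48 (SE 0.47, adjusted p = 0.0402), and its difference was 3.73 with an adjusted p of 0.126 with slide as a block. PLPPR4, a phospholipid phosphatase-related membrane protein, rose by 2.26 (SE 0.31, adjusted p = 0.0450), and its difference was 2.50 with an adjusted p of 0.0786 with slide as a block. A second PLPPR4 probe was well above background on 0 arrays, so the rise rests on 1 probe. RGPD5 of the RANBP2-like family rose by 4.01 (SE 0.50, adjusted p = 0.0283) on its brighter probe, while a second probe gave 0.28 for this gene of a multi-copy family. No long non-coding feature rose.

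RPL39L fell by 11.23 (SE 0.31, n = 3 and 4, adjusted p = 4.43e-05), from 3.63 (SD 0.34) in TAL to a level not well above background in TLX, at least 617-fold. NDN fell by 10.18 (SE 0.27, adjusted p = 4.43e-05), at least 322-fold, with the 4 TAL lines at 2.70 (SD 0.06). ANXA5, a phosphatidylserine-binding protein, fell by 11.09 (SE 0.83, adjusted p = 0.00345), at least 578-fold. PSAT1 was well above background in all 7 lines and fell by 9.60 (SE 0.55, adjusted p = 0.000919), 776-fold, from 6.21 (SD 0.54) to -3.39 (SD 1.05). TMSB15A, an actin monomer-binding thymosin, fell by 10.61 (SE 1.03, adjusted p = 0.0114), at least 481-fold. FA2H, a fatty acid hydroxylase, fell by 10.51 (SE 1.08, adjusted p = 0.0127), at least 625-fold.

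SKAP1, an adaptor between the T-cell receptor and integrins, fell by 9.92 (SE 0.54, adjusted p = 0.000861), at least 674-fold. BEND4 fell by 9.48 (SE 0.35, adjusted p = 0.000117). KRT1, a keratin, fell by 9.39 (SE 1.18, adjusted p = 0.0298) and COTL1, an actin-binding protein, fell by 9.23 (SE 1.08, adjusted p = 0.0222), each well above background in 1 of the 3 TLX lines. With slide as a block the difference was -8.87 for SKAP1 (adjusted p = 0.161) and -10.58 for BEND4 (adjusted p = 0.0650). Long non-coding features gave 16 of the 93 lower ones. CUST_19762_PI427704219 (ENST00000564194) fell by 8.50 (SE 0.63, adjusted p = 0.00341), at least 155-fold, and CUST_8726_PI427704219 (ENST00000565689) fell by 7.30 (SE 0.55, adjusted p = 0.00359), at least 61.6-fold. Of the 77 named genes past the threshold, 13 had more than 1 probe. Of these, 12 further probes were well above background, all 12 of the same sign, though not always of like size.

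MSRB3, PCDH9, KLF6, RPL39L, ANXA5, NDN, PSAT1 and TAL1, with the 2 long non-coding features above, stayed past the threshold when the row of the array on the slide was made a block, a fit that left 25 features, 5 of them higher in TLX. That fit took all 10 arrays, which without a block gave 85 features (8 higher). With slide as a block, also on all 10 arrays, the count was 177 (16 higher). On slide 1 alone, which leaves CCRF-CEM out, it was 249 (20 higher). Leaving out HPB-ALL gave 187. The number higher in TLX was 2 of 68 without DND-41, 4 of 72 without ALL-SIL, 17 of 187 without HPB-ALL and 26 of 106 without JURKAT. Values of TLX and TAL did not overlap for 2681 features, 10.6% of the 25386 with a value on all 7 arrays, where a chance order of 7 values gives 5.71%, and 2394 features had an unadjusted p under 0.05. The median log2 difference of all tested features was 0.11 in this scaling, 0.13 after quantile normalization and -0.13 when the percentile was taken over probes well above background on all arrays.

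**Figure D2:**
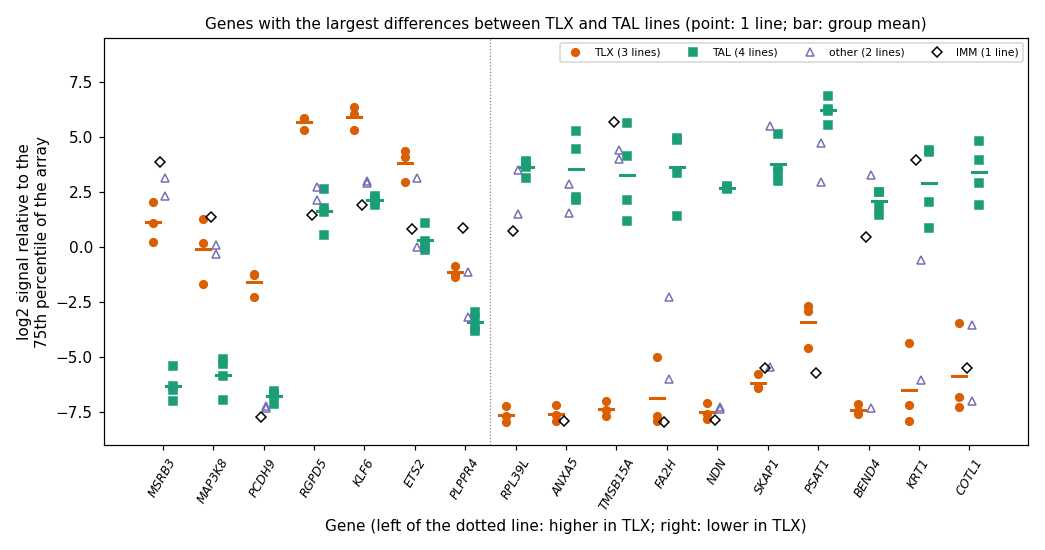
Log2 levels of the named genes with the largest differences in each line, higher in TLX on the left and lower in TLX on the right, with bars at the group means. RPL39L fell by 11.23 and NDN fell by 10.18 with little spread within the groups, and MSRB3 rose by 7.43.

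Of the 20 fixed lists, 3 shifted between TLX and TAL with the preset correlation and 0 with an estimated one. The rotation test fry passed NKL-class homeobox genes (adjusted p = 0.0230), the TAL1 complex list and Early T-cell precursor and stem cell genes (adjusted p = 0.0371 each), but not Proliferation (adjusted p = 0.365). The list TAL1 complex and its described targets was lower in TLX (median -0.61, adjusted p = 0.0380, and adjusted p = 0.299 with an estimated correlation). Of its 18 tested members 2 fell. TAL1 fell by 7.73 (SE 0.55, adjusted p = 0.00304, at least 91.8-fold) and ALDH1A2, an enzyme of retinoic acid synthesis, fell by 9.16 (SE 0.82, adjusted p = 0.00690, at least 265-fold), and 16 were not past. TAL1 is the gene behind the label TAL, so its fall follows from the grouping, and the list was not tested without it. With slide row as a block ALDH1A2 was -6.31 with an adjusted p of 0.110. Adjusted over the list alone there were 4, among them STIL, a mitotic spindle gene (1.37, adjusted p over all genes 0.289). The adjusted p of the list was 0.222 with slide as a block, 0.141 on slide 1 alone and 0.366 with slide row as a block. NKL-class homeobox genes were also lower in TLX (15 tested, median -0.24, mean -1.83, adjusted p = 0.00594, and 0.290 with an estimated correlation). Here 0 members were past over all genes and 4 over the list alone, led by TLX2 (-7.63, adjusted p = 0.0540) and DLX4 (-6.67, adjusted p = 0.0554), with NKX3-2 at -6.01. DLX4 was past over all genes with slide as a block (-7.18, adjusted p = 0.0114) and without CCRF-CEM (adjusted p = 0.0131), but not with slide row (-6.64, adjusted p = 0.243). Slide as a block gave the list 0.0209, slide 1 alone 0.00892 and slide row 0.0618. TLX1 and TLX3 belong to this list but were on too few of the 7 arrays to be tested, and with no filter on dim probes the adjusted p was 0.148 in the same direction, so the call depends on the filter.

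Proliferation genes were higher in TLX as a list (23 tested, median 0.63, 23 of 23 above 0, adjusted p = 0.00126), and the adjusted p was 0.552 with an estimated correlation, which was 0.697 between these genes. The shift came from JURKAT (list mean 3.59) and KE-37 (3.70), whereas PF-382 (4.63) and CCRF-CEM (4.82) lay close to the TLX lines (4.69 to 4.99). MKI67, a marker of cycling cells, differed by 1.03 (adjusted p = 0.420) and TYMS, an enzyme of thymidylate synthesis, by 0.90 (adjusted p = 0.459), so 0 members were past over all genes or over the list alone. The adjusted p of the list was 3.36e-05 with slide as a block, 2.47e-05 on slide 1 alone, 0.00655 with slide row and 0.0530 after quantile normalization.

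Early T-cell precursor and stem cell genes had 18 tested members, of which 1 fell. MYCN, a proto-oncogenic transcription factor, fell by 7.69 (SE 0.76, adjusted p = 0.0118, at least 69.0-fold), and was also the 1 past over the list alone. With slide row as a block its difference was -7.46 with an adjusted p of 0.0743. NFE2 (-6.22, adjusted p = 0.346) and KIT (-5.25, adjusted p = 0.395) were not past, but without CCRF-CEM the receptor gene KIT was (-6.80, adjusted p = 0.0117), though not with slide (adjusted p = 0.170) or slide row (adjusted p = 0.769) as a block. The median of the list was -0.22 and its adjusted p 0.0531. Among Myeloid markers, CEBPE, a granulocyte transcription factor, fell by 7.97 (SE 0.98, adjusted p = 0.0276), the 1 of 11 members past over all genes and over the list. Its difference was -7.02 with slide as a block (adjusted p = 0.167) and -5.22 with slide row (adjusted p = 0.669). FCER1G (0.64) and CST3 (-4.46) were not past, and the list had a median of -0.20 and an adjusted p of 0.169.

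The other 15 lists had 0 members past over all genes. IL7R, JAK and STAT signalling had 18 tested members, a median of 0.56 and an adjusted p of 0.0645 (0.0491 with slide as a block, 0.0137 with slide row), and PIM1, a kinase gene induced by cytokines, was past over the list alone (4.32, adjusted p over all genes 0.0907), with IL7R at 4.71 and SOCS1 at 3.50 not past. Recurrently mutated or deleted T-ALL genes had 27, a median of 0.46 and an adjusted p of 0.158, with EZH2 at 0.79. Interferon response had 23, a median of 0.58 and an adjusted p of 0.169, with MX2 at 3.13 and IFIT3 at 3.03, and 0 past over the list. HOXA cluster and cofactors had 11, a median of 0.68 and an adjusted p of 0.169, with HOXA3 at 2.95 and HOXA4 at 2.25. NOTCH1 targets had 20, a median of 0.54 and an adjusted p of 0.235, with NOTCH1 itself at 1.04, and 0 past over the list. Over 17 other settings, camera with the preset correlation put IL7R, JAK and STAT signalling past the threshold in 8. Early T-cell precursor genes, Interferon response and HOXA genes were past in 3 each, and NOTCH1 targets in 2. Apoptosis regulators, Myeloid markers and Recurrently mutated or deleted T-ALL genes were past in 1 each.

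Apoptosis regulators had 20 tested members, a median of 0.31, a mean of -0.19 and an adjusted p of 0.235 upward, and the BH3-only genes HRK (-6.57, adjusted p = 0.101) and PMAIP1 (1.97, adjusted p = 0.173) were past over the list alone. MHC class II and its regulators had 6, a median of -0.19 and an adjusted p of 0.235, with HLA-DMB at -2.01. NK and cytotoxic markers had 10, a median of -0.44 and an adjusted p of 0.233, with NCAM1 at -5.13 and GZMH at -2.96. Erythroid and megakaryocyte markers had 7, a median of -0.09 and an adjusted p of 0.394, with KLF1, an erythroid transcription factor, at -0.83. B-cell markers had 10, a median of 0.85, a mean of 0.20 and an adjusted p of 0.790, with IGLL1 at 1.92 and VPREB1 at -5.18.

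Cortical thymocyte genes had 22 tested members, a median of -0.24 and an adjusted p of 0.896, with CD1B at 3.38 (adjusted p = 0.415) and CD4 at 1.18. T-cell receptor and proximal signalling had 23, a median of -0.35 and an adjusted p of 0.896, with CD7 at 3.01 and CD247 at 1.23. Homing and adhesion receptors had 23, a median of 0.09 against a test pointing downward at an adjusted p of 0.851, and the chemokine receptor CXCR5 (1.96, adjusted p = 0.127) and the integrin ITGB1 (1.52, adjusted p = 0.186) were past over the list alone. Long non-coding RNAs had 33, a median of 0.03 against a test pointing downward at an adjusted p of 0.579, with CYTOR at 2.62 and MIR17HG at 0.67. Stromal and epithelial markers had 5, a median of -0.15, a mean of 0.27 and an adjusted p of 0.782, and PDGFRB (6.27, adjusted p = 0.0921) and COL1A1 (-4.05, adjusted p = 0.411) were past over the list alone.

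KARPAS-45 and PEER, the lines labelled other, were set against the mean of TLX and TAL. COL2A1, a cartilage collagen, rose by 8.01 (SE 0.37, n = 2 against 7, adjusted p = 0.000690), at least 71.1-fold, though LOUCY, outside this comparison, was higher still at 3.57, and RAG2, a recombinase of antigen receptor genes, fell by 7.10 (SE 0.71, adjusted p = 0.0362), at least 51.8-fold, from 0.25 (SD 0.93) in the 7 lines to -6.83 (SD 0.69). SHISAL1, a membrane protein gene, rose by 6.38 (SE 0.71, adjusted p = 0.0453), at least 22.7-fold. CA8, a carbonic anhydrase-related gene, rose by 6.93 (SE 0.81, adjusted p = 0.0487), MSRB3 by 5.29 (SE 0.57, adjusted p = 0.0453) and RPL39L by 4.49 (SE 0.52, adjusted p = 0.0487). NDN fell by 4.92 (SE 0.29, adjusted p = 0.00149), the zinc finger gene ZDBF2 fell by 3.53 (SE 0.42, adjusted p = 0.0498) and PCDH9 fell by 3.07 (SE 0.36, adjusted p = 0.0498). CA8, MSRB3, RPL39L, NDN, ZDBF2 and PCDH9 also differed between TLX and TAL, so these 6 compare KARPAS-45 and PEER with a mean of unlike groups.

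COL2A1 and NDN stayed past the threshold with slide as a block and with slide row as a block. In total 19 of 30176 features were past, 13 higher and 6 lower, and 12 had a gene symbol, while 1597 had an unadjusted p under 0.05. With slide as a block 10 were past (7 higher), with slide row 5 (4 higher), and on slide 1 alone, 69. The count depended on most lines, as it was 120 without PEER, 41 without KARPAS-45, 6 without DND-41 or HPB-ALL, 7 without PF-382, 4 without JURKAT and 11 without CCRF-CEM, and it moved less without ALL-SIL (13) or KE-37 (14). On slide 1 alone, without PEER or without KARPAS-45 the group is a single array and TLX and TAL supply the whole spread, so the counts of 69, 120 and 41 say little about the group.

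LOUCY stood apart by CLDN5, a tight junction protein, at 4.02 and at least 620.0-fold over the other 9 lines, and by the missing signal of MYC, a growth-promoting transcription factor, at -7.70 against 4.66 to 6.95, at least 3592-fold. PAX2, a kidney developmental factor (at least 266-fold), LYN, a SRC-family kinase of B and myeloid cells (4.12, at least 504-fold), and MEF2C, a transcription factor of lymphoid and myeloid progenitors (3.84, at least 345-fold), also stood above. So did PTGS1, a prostaglandin synthase (1.17, at least 86.6-fold), PHACTR3, a phosphatase regulator (at least 150.1-fold), KLRK1, an NK-cell receptor (0.40, at least 50.8-fold), and PLD4, a phospholipase-family gene (0.11, at least 41.5-fold). LINC01257 (0.05, at least 39.9-fold) and CXCR2P1 (-0.20, at least 33.4-fold) were the non-coding ones among the named genes, and CUST_10926_PI427704219 (TCONS_00020657, 1.29, at least 94.2-fold) had the widest gap above of all long non-coding features.

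EZH2, a histone methyltransferase, stood at -7.04 in LOUCY against 4.06 to 5.37 in the other 9 lines, at least 1672-fold. DYNLT1, a dynein light chain (at least 791-fold), EMC10, a membrane protein insertion factor (at least 676-fold), SDHAF3, an assembly factor of succinate dehydrogenase (at least 654-fold), and UBE2E3, a ubiquitin-conjugating enzyme (at least 332-fold), were also below. Further down were CCNC, a cyclin of the Mediator complex (at least 293-fold), SLAIN1, a microtubule-binding protein (at least 216-fold), SPAG16 (at least 193-fold) and CUST_18543_PI427704219 (TCONS_00022861, at least 289.6-fold). MYC, EZH2, DYNLT1, SDHAF3, CCNC and SLAIN1 were each read by a single probe. For these, loss of expression, loss of the gene and a changed probe site cannot be told apart here. Both probes of EMC10 and both of UBE2E3 were low.

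In LOUCY 1032 features lay above and 439 below the range of the other 9 lines by at least 1 log2 unit, 1471 in total, and 433 of those above and 163 of those below were long non-coding. This number is not unusual, as JURKAT had 1730, HPB-ALL 1514, KE-37 1454, KARPAS-45 1392, PF-382 882, PEER 837, ALL-SIL 800, DND-41 654 and CCRF-CEM 499. On slide 1 alone, with fewer lines to exceed, LOUCY had 1964. As 1 array stands for LOUCY, no test was made.

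LOUCY was high in genes of early precursors and low in genes of cortical thymocytes. The percentiles below are not a test, because the random lists lack the shared variation of genes in a fixed list. Early T-cell precursor and stem cell genes had a median of 3.26 over the mean of the other lines, higher than in 100% of random lists matched on level, and 7 members lay above the range and 0 below, among them IGFBP7 (3.81 against at most 0.69), SPI1, a myeloid master regulator (1.68 against at most -2.22), MEF2C and MYCN (3.47 against at most 1.49). HOXA cluster and cofactors had a median of 3.11 (percentile 100) with 6 above, including HOXA5 (2.23 against at most 1.04) and HOXA9. The mean level of this list was 0.00 in LOUCY and -0.67 in JURKAT, the next highest line. Myeloid markers had a median of 1.92 (percentile 100) with 6 above, including CSF1R, the receptor for macrophage growth factor (-0.87, at least 18.3-fold), the integrin ITGAM (0.63, 10.4-fold), CST3 (2.83) and FCER1G (2.24). NK and cytotoxic markers had a median of 2.07 (percentile 100) with TBX21, a T-box transcription factor, above (0.75). Their mean level was -2.42 in LOUCY, close to -2.73 in KE-37 and -2.83 in JURKAT. B-cell markers had a median of 0.93 (percentile 99.9) with VPREB1, a surrogate light chain, above at 7.09 against at most 4.70. For B-cell markers the mean level was -0.17 in LOUCY and -0.58 in DND-41, the next highest line.

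Cortical thymocyte genes had a median of -4.37 in LOUCY, lower than in all random lists (percentile 0), with 5 below the range and 0 above. TCF7, a T-cell transcription factor, stood at -6.28, at least 2327-fold under the mean of the others and low on both of its probes. DNTT, which adds nucleotides to receptor genes, was lower by at least 129-fold, CCR9, a chemokine receptor, by at least 58.6-fold, CD8A stood at -4.72 and BCL11B, a T-lineage factor, at 2.87 against at least 4.13. NOTCH1 targets had a median of -1.79 (percentile 0) with MYC, LZTFL1 (-1.65) and NOTCH3 (-3.92) below and HEY1 (-1.86) above. Interferon response had a median of -0.60 (percentile 0.300) with XAF1 (at least 160.5-fold), MX1 (-2.51 against at least 0.24) and IFIT3 (at least 22.7-fold) below. Stromal and epithelial markers had a median of -1.47 (percentile 0.910) with 0 outside. Over the main scaling and 4 others the median ran from -4.37 to -3.12 for cortical thymocyte genes, from 2.52 to 3.36 for early precursor genes, from 1.96 to 3.21 for HOXA genes, from 1.22 to 1.97 for myeloid markers, from 0.61 to 2.13 for NK and cytotoxic markers, from -1.79 to -1.17 for NOTCH1 targets and from -1.47 to -0.43 for stromal and epithelial markers. Among lists nearer 0 it ran from 0.21 to 0.61 for erythroid and megakaryocyte markers, from 0.09 to 0.34 for NKL-class genes and from 0.11 to 0.33 for MHC class II.

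The TAL1 complex list had a median of 0.82 in LOUCY (percentile 99.99) with LYL1 and GATA2 (-0.84) above, although TAL1 itself was not well above background there. The mean level of this list was 2.12 in LOUCY, close to 2.03 in CCRF-CEM and 1.76 in PEER. Apoptosis regulators had a median of 0.40 (percentile 99.8) and 0 outside. Erythroid and megakaryocyte markers had 0.50 (percentile 95.02) with the integrin ITGA2B above (1.01 against at most -3.15). NKL-class homeobox genes had 0.29 (percentile 96.8), MHC class II and its regulators 0.27 (79.5), both with 0 outside, and IL7R, JAK and STAT signalling 0.11 (84.2) with IL2RA above. Homing and adhesion receptors had a median of -0.00 (percentile 65.3) with CXCR4 (5.50 against at least 6.65) and CCR9 below, and Long non-coding RNAs one of -0.08 (48.0) with HOXA11-AS (3.24) above and SNHG1 (4.92 against at least 6.01) below. The sign of these 2 medians turned with other scalings, to 0.04 to 0.08 and to 0.00. T-cell receptor and proximal signalling had -0.13 (33.3) with THEMIS (at least 98.2-fold) and TRAT1 (0.18) below, Proliferation -0.24 (11.4) with 0 outside, and Recurrently mutated or deleted T-ALL genes -0.25 (9.97) with EZH2, WT1, CDKN1B, USP7 and BCL11B below.

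**Figure D3:**
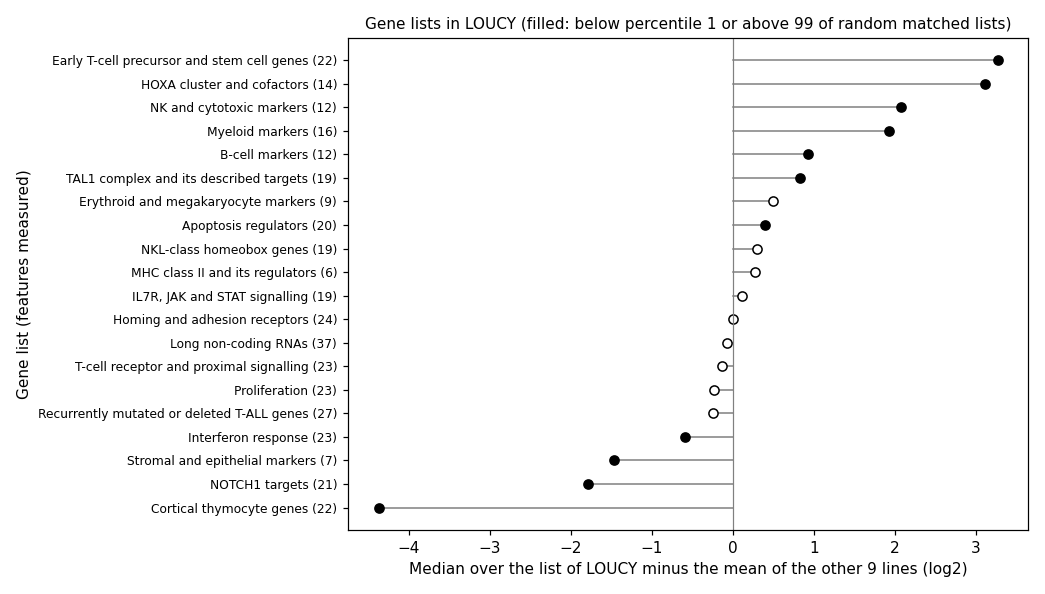
Median log2 difference between LOUCY and the mean of the other 9 lines for the 20 lists, filled where the median lay under the 1st or over the 99th percentile of random lists. Early T-cell precursor and stem cell genes stood at 3.26 and Cortical thymocyte genes at -4.37.

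Long non-coding features were detected less widely than coding ones. Of 24069 long non-coding features 13438 (55.8%) were well above background in at least 1 line, 3896 (16.2%) in all 10 and 3748 (15.6%) in exactly 1. Of 18143 coding features 87.4%, 58.7% and 6.32% were. The median line had 30.4% of the long non-coding features, from 24.2% in CCRF-CEM to 32.7% in LOUCY, against 71.7% of the coding ones. Between TLX and TAL 16 of 7156 tested long non-coding features were past the threshold (0.224%), all lower in TLX, against 74 of 13480 coding ones (0.549%, 8 higher and 66 lower). The odds ratio was 0.406 (95% interval 0.221 to 0.704, Fisher's exact p = 0.000518), while the median size of the difference was 0.42 in long non-coding and 0.41 in coding features. Fisher's test takes features as independent, so its interval and p do not measure the spread between lines. The tested long non-coding features were dimmer, with a median level of -3.00 against 1.12, and the shares with an unadjusted p under 0.05 were close (9.26% and 10.1%). The number of long non-coding features past was 39 with slide as a block, 5 with slide row as a block and 53 on slide 1 alone, without CCRF-CEM. It was 30 without HPB-ALL, 31 without JURKAT, 8 without DND-41 and 7 without ALL-SIL.

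On average the TLX lines and the TAL lines resembled their own group more than each other. The mean correlation was 0.893 within groups and 0.862 between them, a difference of 0.0303, the highest of the 35 splits of the 7 lines (exact permutation p = 0.0286, the smallest this design allows), and the next highest split gave 0.0224. With coding features alone the difference was 0.0425 (exact p = 0.0286) and with long non-coding features alone 0.0267 (exact p = 0.0571). On slide 1 alone, without CCRF-CEM, it was 0.0367 (exact p = 0.100, the smallest possible there). The most alike pair was PEER and CCRF-CEM (0.936), the 2 arrays of slide 2, followed by JURKAT and PF-382 (0.916) and by ALL-SIL and DND-41 (0.906), and the least alike was ALL-SIL and JURKAT (0.830). Single pairs did not all follow the groups. HPB-ALL correlated at 0.880 with PF-382, a TAL line, against 0.879 with DND-41 and 0.872 with ALL-SIL, and DND-41 correlated at 0.881 with CCRF-CEM. ALL-SIL and DND-41 shared slide row 1 while HPB-ALL lay in row 2 with the TAL lines, and the permutation takes no account of the row. KARPAS-45 and PEER, which share the label other, correlated at 0.856.

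**Figure D4:**
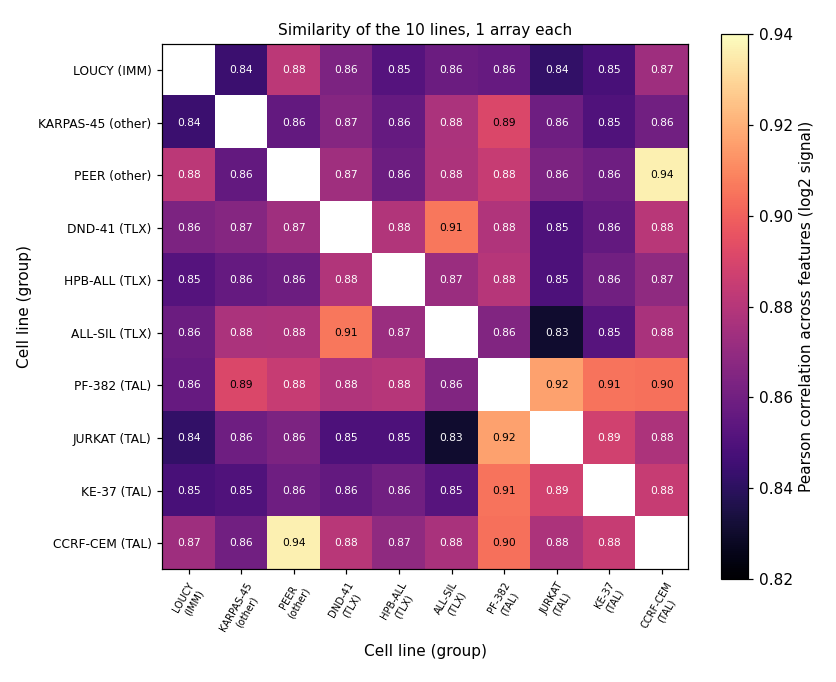
Pearson correlation of log2 levels between the 10 lines, ordered by group. PEER and CCRF-CEM were most alike (0.936) and ALL-SIL and JURKAT least alike (0.830).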

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

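For 89 values reported in the text, each line of a group of 4 was checked by Dixon's test, which singles out 1 line far from 3 that lie close together, and 6 of the 89 (6.74%) were singled out. Chance alone flags about 1 in 20 groups, so 6 is close to what chance gives, and all 6 concern TAL lines, the only group with 4. Where the other 3 lines lie very close together, a small distance is enough.

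NKX2-1 stood at 2.05 in JURKAT against -6.96 to -6.42 in the other 3 TAL lines, where it was not well above background, the largest distance of the 6. SOCS1, a brake on cytokine signalling, stood at 1.40 in KE-37 against -1.13 to -0.91. ALDH1A2 stood at 1.12 in KE-37 against 2.72 to 2.94, still above the TLX lines. The long non-coding feature CUST_19762_PI427704219 stood at 0.43 in CCRF-CEM against 1.89 to 2.14. The mean of the IL7R, JAK and STAT signalling list stood at -0.35 in JURKAT against 0.45 to 0.59. NDN stood at 2.79 in KE-37 against 2.66 to 2.68, a distance of little weight that was singled out because the other 3 lines were nearly equal. No line was left out for these values.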

How the results depend on the processing

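The 26 genes and long non-coding features named from the TLX against TAL comparison gave 459 values under other settings. All 459 kept their direction, 377 were also past the threshold and 82 were not. Most of the 26 were chosen for large differences without overlap between TLX and TAL. Leaving out a line cannot turn the sign of such a difference, so the kept direction adds no support. The counts did move. After normexp and quantile normalization the TLX against TAL count was 51 (102 in the main setting), the long non-coding count 2 (16), the named features past 17 (26), the count for the lines labelled other 12 (19) and that for LOUCY 815 (1471). The percentile over probes well above background on all arrays gave 6 shifted lists (3) and 7 features for the lines labelled other, the deposited log2 table gave 8 for the latter, no filter gave 7 lists and 8 features, 1 fit of all 10 arrays gave 5 lists, and the trend and robust prior gave 11 features for the lines labelled other. Slide as a block gave 177 for TLX against TAL, 39 long non-coding and 10 for the lines labelled other. Slide row as a block gave 25, 5 and 5, with 11 named features past. Slide 1 alone gave 249 for TLX against TAL and 69 for the lines labelled other. A gap of at least 2 gave 668 for LOUCY, lower by construction. Long non-coding features alone gave a correlation difference of 0.0267 (exact p = 0.0571). Leaving out 1 line at a time gave 68 to 249 for TLX against TAL, 7 to 53 long non-coding, 14 to 25 named features, 2 to 6 lists, 4 to 120 for the lines labelled other and a correlation difference of 0.0219 to 0.0381, with exact p of 0.0667 or 0.100, the smallest possible with 6 lines. Signs turned only for values past the threshold neither in the main setting nor in the alternative. HOXA9 was -0.0369 with the percentile over detected probes and -0.54 with the mean of its probes, and with slide row as a block LMO2 was 0.0920. Leaving out lines took LYL1 from -0.68 to 1.79. Lists that turned had these adjusted p-values from camera. With the percentile over detected probes it was 0.653 for Cortical thymocyte genes, 0.872 for Homing and adhesion receptors and 0.806 for T-cell receptor and proximal signalling. With no filter it was 0.205, 0.186 and 0.205 for these lists and 0.300 for Long non-coding RNAs, and with the strict filter 0.705 for NK and cytotoxic markers. Slide as a block gave 0.460 for Homing and adhesion receptors and 0.863 for T-cell receptor and proximal signalling. Slide row gave 0.426 for Cortical thymocyte genes and 0.761 for the latter 2 lists. Leaving out lines gave 0.222 to 0.997 for Cortical thymocyte genes, 0.134 to 0.916 for Homing and adhesion receptors and 0.655 to 0.905 for T-cell receptor and proximal signalling. Apart from the wider gap, the cause was not tested. No paired analysis was possible because the lines are different cell lines and replicate numbers follow only the order of deposition. Signal over background limits folds, as normexp with an offset narrows differences against dim signals.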

Other observations

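Of the tests below, both mixed-RNA tests, the tests of the shared slide and of the slide row in their present form and the 35 splits were chosen after the result was seen, as were slide row as a block, slide 1 alone, slide as a block for the lines labelled other, the similarity by class of feature and the list medians of LOUCY under other scalings.

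The TLX lines were low in 3 enzymes of amino acid synthesis, while others of the same pathways, such as PHGDH (-0.26), PSPH (0.99) and ALDH18A1 (-0.06), were not past the threshold. PSAT1 of the serine pathway fell by 9.60 (adjusted p = 0.000919), PYCR1 of the proline pathway fell by 8.90 (adjusted p = 0.000117) and ASNS, which makes asparagine, fell by 2.68 (SE 0.36, adjusted p = 0.0402), from 6.01 (SD 0.46) to 3.33 (SD 0.44). These enzymes are targets of ATF4, a factor induced by amino acid shortage, so a weaker ATF4 response might link them. The other 26 genes of the ATF4 list, ATF4 itself (-0.05) among them, had a median difference of -0.0949 with quartiles of -0.53 and 0.46. Of these, 17 of 26 were below 0 and 0 were past the threshold, and camera with the preset correlation gave p = 0.227. The values argue against a fall of the list as a whole. CBS (-7.40), GPT2 (-6.09), VLDLR (-3.56) and CHAC1 (-1.71) pointed the same way as the 3 enzymes, and a fall of some targets only was not tested.

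In LOUCY, features below the range of the other lines lay next to each other more often than in shuffled orders. There were 20 neighbouring gene pairs both below, against a median of 4 and a maximum of 13 in 1000 shuffles. Pairs included LZTFL1 with CCR9, DYNLT1 with EZR and SDHAF3 with ASNS. Chromosome 6 had the most genes below, 29 of 633 detected with 0 above, and 5 of the 18 runs of neighbours. Loss of chromosome segments might account for some of them, but 6 other lines were also above their shuffled maximum, among them KARPAS-45 with 22 pairs and ALL-SIL with 16, and neighbours may share regulation, so this stays open.

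The count of 102 features between TLX and TAL could be due to chance in how 7 lines fell into groups or to the position of the arrays on the slide. Of the 35 possible splits 2 gave as many features, the real one with 102 and 1 with 141 that sets CCRF-CEM with the TLX lines, so chance cannot be excluded for the count. With the slide row in the fit 23 of the 102 calls stayed past the threshold in the same direction, so for these the row, as estimated there, is unlikely to be the whole cause. The row effect in that fit rests on few arrays, HPB-ALL against DND-41 and ALL-SIL, and PEER against KARPAS-45 across slides. That fit took all 10 arrays, where the 102 calls came from 7. A fit of all 10 arrays without the row gave 85 features and kept 68 of the 102. The end of the other 79 calls can thus not be laid to the row alone. Their median SE widened from 0.58 to 0.98, and the median size of their differences went from 5.93 to 5.41. The median ratio of these differences after to before was 0.961. For these calls the row, the group and the added arrays cannot be told apart. A test of row written before the result, LOUCY and KARPAS-45 (row 1) against PEER (row 2) over the features lower in TLX (median -1.54), was dropped because it set 2 lines against 1, without a spread between lines, and ran across slides.

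PEER and CCRF-CEM, of different labels, were the most alike pair, and they shared a slide and a scan day. For each pair, features were compared that were on (well above background and over the 75th percentile of the array) in at least 2 of the other 8 lines and off (not well above background) in at least 2, and 75.5% of 628 were in the same state of detection in PEER and CCRF-CEM, against 73.2% in the best pair of slide 1 (JURKAT with KE-37). The excess of 2.28 points is within 2 binomial standard errors (1.72 each), so slide and cell line cannot be told apart, as slide 2 holds only these 2 arrays. Carry-over of RNA could also make them alike, but this was argued against, as 38 features of 6775 bright in PEER were more than 64-fold dimmer in CCRF-CEM and 33 of 6819 the other way, which limits mixing to 1.56%.

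More features were lower (93) than higher (9) in TLX, which might come from the narrow spread of dim values in a moderated test. A count without that test, by the same definition of on and off, gave 16 features off in the 3 TLX lines and on in the 4 TAL lines, where the other splits gave at most 2. For on in 3 and off in 4 the TLX lines gave 1, and the other splits up to 6. The asymmetry thus does not rest on the test alone, but its size depends on JURKAT, without which 26 of 106 features were higher. It also moved with the setting. The higher features were 8 of 51 after normexp and quantile normalization, 5 of 25 with slide row as a block and 2 of 68 without DND-41.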
